A study of Homo sapiens with 6 samples.

How the data were processed

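RNA-seq libraries of SK-NEP-1 cells were compared between 3 siEHMT2 and 3 siNC libraries. Per the labels' protocols, total RNA was the input and libraries were made with the NEBNext Ultra RNA kit, and no label states a strand setting. Groups and replicate numbers were taken from the sample titles. The titles all name SK-NEP-1, whereas the cell line field carries a running number from sample to sample; the titles were followed and all libraries were treated as SK-NEP-1. The authors deposited a table of FPKM values per gene and library, with the unit named in the file header. The submitters' processing notes name fastp, HISAT2 2.2.1, SAMtools 1.4.1, StringTie 2.2.0 and the build hg19, without roles or order; the annotation is not given in the sources used here.

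Of the 55765 rows, 20030 hold a value with more than 6 decimals, and among tested rows this applies to 98.8% of those with several annotated transcripts and 30.9% of those with 1. Values of several transcripts thus appear to have been combined per gene, by a rule that is not given in the sources used here. Whole reads could not be recovered and no count model was used. FPKM is relative to the total of each library, so a few very abundant genes can shift all others, and reads that fit overlapping genes are divided by the upstream program.

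Rows with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as a linear model without covariates and with a mean-variance trend, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The pseudocount of 1 makes the fold changes of low genes smaller than the ratio of their means. The smallest p an exact permutation of 3 against 3 libraries can give is 0.1, so single genes were not tested that way. A total of 35 gene lists with 858 entries was fixed before the data were examined; 11 entries were matched through RefSeq synonyms and 1 was not found. The 30 lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the lists. With an estimated correlation no list was called. The estimate was 0.0532 for the G2/M list and 0.0054 for the WNT/beta-catenin list. The latter lies below the preset 0.01, so a higher correlation does not account for that list's lost call. Its unadjusted camera p was 0.000124 with the preset and 0.0172 with the estimated correlation. With an estimated correlation, camera takes its degrees of freedom from the few libraries rather than from the genes. Its power is then low, so a lack of calls is weak evidence against a list. The test fry asks whether the members of a list move on balance one way and compares it with no other genes. With fry, 3 lists had an adjusted p under 0.05: the G2/M and WNT/beta-catenin lists (0.0221 for both) and the EWSR1-FLI1 activated genes (0.0319).

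The rule for named genes was fixed before the data were examined. It took EHMT2 and EHMT1; the 10 largest rises and 10 largest falls among protein-coding genes past the threshold whose groups do not overlap and whose higher group has a mean of at least 2 FPKM; and from each list the 4 members with the smallest adjusted p past the threshold, or the 2 with the smallest p where none passed. Other members named because they passed when adjusted over their list alone, the overlapping partner genes and the single lineage markers were chosen after their values were seen. Gene types, transcript GC content (median over the transcripts of a gene, available for 91.2% of tested genes) and synonyms came from GENCODE release 29 and RefSeq, matched by symbol. These references are on another build than the files, so no coordinates are given.

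The limma step was tested on simulated data for this comparison, with 12859 genes of the observed means and spreads of which 200 were changed, in 20 simulations. It recovered 22.9% of genes changed by 0.5 on the log2 scale, 75.4% of those changed by 1, 92.5% by 1.5 and 97.4% by 2, and 4.9% of its calls were false. Genes varied independently in these simulations, with the same spread in each library. The 0.33% of unchanged lists called there thus does not bear on lists whose members vary together. The real libraries differ in spread (gene-by-gene array weights of 0.278 to 3.77), and another split of them called 35 genes. The recovered shares and the 4.9% therefore do not carry over to the genes called in the data. Alternatives fixed before the data were examined were other pseudocounts, filters and scalings, no trend, array weights, a replicate block, rows of 1 symbol summed, other list tests and each library left out. A correction for GC content (loess per library, span 0.5), the genes with a GC value, the block with the GC correction, gene-by-gene array weights, protein-coding genes alone, both libraries numbered 3 left out, and each alternative with an estimated correlation of list members were added after the data were seen. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.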

Results

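Total RNA was sequenced from SK-NEP-1, a cell line that the submitters label as a Wilms tumor line of the kidney, after treatment with a small interfering RNA against EHMT2 (siEHMT2) or a control small interfering RNA (siNC), with 3 libraries in each group. EHMT2 encodes a histone methyltransferase that, together with its partner EHMT1, places methyl groups on lysine 9 of histone H3. The comparison addressed which transcripts differ when EHMT2 is targeted. Values were FPKM per gene, fragments normalized to transcript length and to the mapped fragments of the library, for 55765 gene names, of which 12859 had a mean of at least 1 FPKM over the 6 libraries and were tested. The FPKM of a library summed to between 244702 and 272271, and mitochondrially encoded transcripts took 19.03% to 23.59% of that sum. The absolute depth is unknown, because whole read counts could not be recovered from these values. The most frequent value above 0 among short RNA genes, taken as a step of coverage, put the relative depth of the libraries between 90.7% and 100% of the deepest. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

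EHMT2 was lower in the siEHMT2 group, at 10.7 ± 4.81 FPKM (SD, n = 3) against 25.8 ± 2.67 in siNC, or 0.415 of the control mean. The 3 siEHMT2 libraries held 7.61, 8.26 and 16.2 FPKM and the siNC libraries 27.5, 27.2 and 22.7, so every siEHMT2 library lay below every siNC library, and siEHMT2 replicate 3 kept the most EHMT2 of its group. The log2 fold change was −1.27 ± 0.24 (SE) on the log2(FPKM + 1) scale, and its limma adjusted p of 0.0609 missed the threshold of 0.05. Without siEHMT2 replicate 3, the library of its group with the most EHMT2, it was −1.58, with an adjusted p of 0.0163. Without any of the other 5 libraries it was −1.35 to −1.08 and did not pass, with adjusted p from 0.0857 to 0.259. Over all alternatives the adjusted p ranged from 0.000364 to 0.259. EHMT1 was at 9.53 ± 0.306 FPKM against 8.29 ± 0.262 (log2 fold change 0.18 ± 0.09, limma adjusted p = 0.326).

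**Figure D1:**
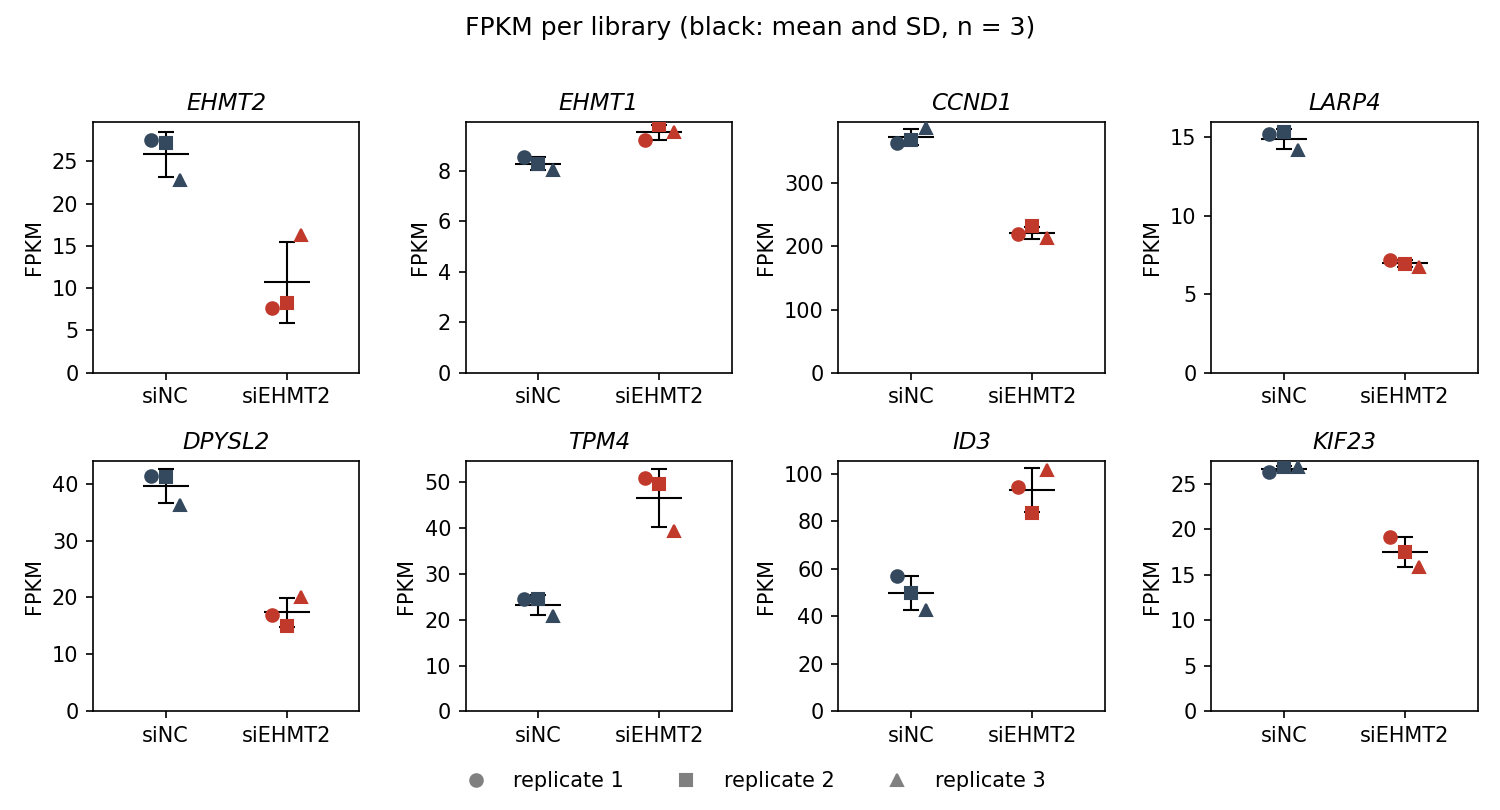
FPKM (y axis, from 0) of 8 genes in the siNC and siEHMT2 libraries (x axis); symbols are replicates 1 to 3, and the black line and bar give the mean and SD of 3 libraries. EHMT2 is at 7.61, 8.26 and 16.2 FPKM in siEHMT2 and between 22.7 and 27.5 in siNC.

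Among the protein-coding genes with the largest rises, ADRA1D, the alpha-1D adrenergic receptor, went from 9.06 ± 0.735 to 21.02 ± 3.30 FPKM (log2 fold change 1.12 ± 0.13, limma adjusted p = 0.0285, n = 3 per group). TPM4, an actin-binding tropomyosin, rose from 23.2 ± 2.17 to 46.6 ± 6.35 FPKM, and ID3, an inhibitor of basic helix-loop-helix transcription factors and a known BMP target, rose from 49.8 ± 7.14 to 93.2 ± 9.17 FPKM. The synapse protein gene SYNDIG1 rose from 1.24 to 4.24 FPKM, the cell surface proteoglycan gene SDC1 from 3.95 to 8.75, the kinesin gene KIF1C from 11.6 to 22.7 and the prolyl isomerase gene FKBP9 from 0.778 to 2.34. Among the largest falls, DPYSL2, which binds tubulin and acts in axon growth, fell from 39.6 ± 2.96 to 17.4 ± 2.55 FPKM (log2 fold change −1.15 ± 0.12, limma adjusted p = 0.0265), ATP1B2, a beta subunit of the sodium pump, from 4.09 to 1.05, and ATCAY, which encodes caytaxin, from 2.63 to 0.664. FERMT3, an activator of integrins, fell from 36.4 ± 8.54 to 16.2 ± 2.94 FPKM. The RNA-binding protein gene LARP4 fell from 14.9 ± 0.626 to 6.96 ± 0.236 FPKM, the splicing factor kinase gene SRPK2 from 8.31 to 4.25, the erythropoietin receptor gene EPOR from 15.7 to 8.76 and the centriole and spindle protein gene CCSAP from 4.02 to 1.97. Of the 25 named genes past the threshold, here and in the lists, limma called 3, 0 and 24 without siEHMT2 replicate 1, 2 or 3 and 0, 0 and 1 without siNC replicate 1, 2 or 3. It called 0 of them without the filter on low values and 14 with the libraries rescaled to the same sum. In each of these fits all 25 kept their direction and an unadjusted p under 0.05. This is no independent support, since the 25 were selected for a small p over the same libraries. Their groups do not overlap, so leaving out a library could not turn their direction.

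Some of the largest values are uncertain, because the genes overlap others or have close copies and the files do not show how reads were divided. The readthrough gene PPAN-P2RY11 was at 1.33 ± 0.760 FPKM against 7.15 ± 3.17 (log2 fold change −1.78), while P2RY11 itself, chosen after its values were seen, was at 12.9 against 7.89 with a limma adjusted p of 0.0878. GDF1 was at 4.11 against 11.9 FPKM (−1.35), whereas CERS1, with which it shares a transcript, was at 3.46 against 2.81 (0.22, limma adjusted p = 0.580). C7orf55 (5.37 against 1.61 FPKM, log2 fold change 1.27) belongs to a readthrough gene, C7orf55-LUC7L2, that was at 29.1 against 27.8. CENPVP3 (1.06) has close copies, and ZBED6CL (1.01) lies within LRRC61.

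In all, 71 of the 12859 genes differed at a limma adjusted p under 0.05, 44 higher and 27 lower in siEHMT2, and 66 of them were protein-coding. Of these, 14 differed at least 2-fold on the log2(FPKM + 1) scale, 7 in each direction. With the libraries rescaled to the same sum, 28 genes were called, 8 higher and 20 lower. The excess of rises over falls thus depended on how the libraries were scaled. Without the filter on low values limma called 0, with 3641 at an unadjusted p under 0.05. The groups did not overlap for any of the 71 genes, nor for 3383 of all tested genes (26.3%, where chance gives 10% on average over the splits). Genes vary together and the shares of the other splits were not computed. The 26.3% therefore does not measure an effect of the siRNA. The count depended on single libraries: it was 5, 0 and 172 without siEHMT2 replicate 1, 2 or 3, and 0, 1 and 4 without siNC replicate 1, 2 or 3, where 1526 to 2708 genes still had an unadjusted p under 0.05. Fold changes also rose with the GC content of the transcript (Spearman rho 0.387 across 11732 genes, which are not independent replicates), and siEHMT2 replicate 3 stood apart in this respect: its deviation from the gene means had a rho of 0.573 with GC, against −0.339 to 0.110 in the other libraries.

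Genes of mitosis were lower as a group. Of 34 tested members of the G2/M and mitosis list, 31 were lower and 3 higher in siEHMT2, with a median log2 fold change of −0.21 (camera with a preset correlation of 0.01, adjusted p = 3.4e-08; adjusted p = 0.258 with an estimated correlation). The list's median was lower in 9 of 9 pairs of an siEHMT2 with an siNC library. These pairs reuse the same 3 and 3 libraries and are not 9 separate comparisons. Averaged over the splits, chance keeps groups of 3 and 3 from overlapping in 10% of cases, and the groups did not overlap for 26.3% of all tested genes. Each of the 10 splits of the libraries into 3 and 3 called at least 2 lists with the preset correlation, and the highest other called 8. The number of called lists thus does not set the real grouping apart. KIF23, a motor protein of cytokinesis, fell from 26.7 ± 0.270 to 17.5 ± 1.68 FPKM (limma adjusted p = 0.0493). It was the only member past the adjustment over all genes. Adjusted over the list alone, 8 members were lower: KIF23, NUF2, TOP2A, PLK1, CCNB1, CDK1, KIF20A and TTK. Such an adjustment does not control errors over all the lists searched. The mitotic cyclin gene CCNB1, for example, was at 43.9 against 59.5 FPKM (log2 fold change −0.44), and the topoisomerase gene TOP2A at 115 against 159 (−0.45). The list of G1/S and DNA replication genes did not show this: 16 of 34 members were higher and 18 lower, the median was −0.02 (camera adjusted p = 0.876), and its members with the smallest p were E2F1 (60.3 against 43.8 FPKM) and RFC4 (16.7 against 20.4), neither past the threshold. Single libraries moved the G1/S median, from −0.07 without siEHMT2 replicate 1 or siNC replicate 2 to 0.06 without siEHMT2 replicate 3 and 0.08 without siNC replicate 3, none of them called. Without both libraries numbered 3, an alternative chosen after the data were seen, the G1/S list was called higher (median 0.15, camera adjusted p = 0.0174; adjusted p = 0.614 with an estimated correlation). Under the other alternatives its adjusted p was at least 0.229.

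WNT/beta-catenin targets were lower as a group too, with 10 of 11 tested members lower and a median of −0.25 (camera with a preset correlation, adjusted p = 0.0019; adjusted p = 0.258 with an estimated correlation). The list's median was lower in 9 of 9 library pairs, which reuse the same libraries and are not separate comparisons. It was −0.15 and −0.17 with both kinds of array weights and −0.14, over 21 members, without the filter on low values, each past the threshold with the preset correlation. The estimated correlation of this list was 0.0054, below the preset 0.01, so a higher correlation does not account for the lost call. The test with an estimated correlation draws its degrees of freedom from the few libraries, which lowers its power. The limit from the other splits of the libraries holds for this list too. CCND1, which encodes cyclin D1 and is a driver of G1 progression, fell from 374 ± 12.4 to 222 ± 10.1 FPKM (log2 fold change −0.75 ± 0.10, limma adjusted p = 0.0287). It was the only member past the threshold, over all genes and adjusted over the list alone. CCND1 is also in the list of genes activated by EWSR1-FLI1, the fusion protein of Ewing sarcoma, of which 18 of 27 members were lower (median −0.16, camera adjusted p = 0.0678, not past the threshold). Without siEHMT2 replicate 3 that list passed (median −0.10, camera adjusted p = 0.0313; adjusted p = 0.641 with an estimated correlation). Without siEHMT2 replicate 1 its median was −0.09 (camera adjusted p = 0.210). With CCND1, BCL11B passed when adjusted over that list alone (15.9 against 24.3 FPKM). The list of genes repressed by EWSR1-FLI1 was mixed: COL5A2, TNC, IGFBP3 and CYR61 were higher and CAV2 and FOSL1 lower when adjusted over the list alone, and the list as a whole did not pass (6 higher and 5 lower, median 0.23, camera adjusted p = 0.876). Its median depended on single libraries. It was 0.10, 0.14 and 0.42 without siEHMT2 replicate 1, 2 or 3 and 0.08, 0.17 and 0.34 without siNC replicate 1, 2 or 3. None of these passed.

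**Figure D2:**
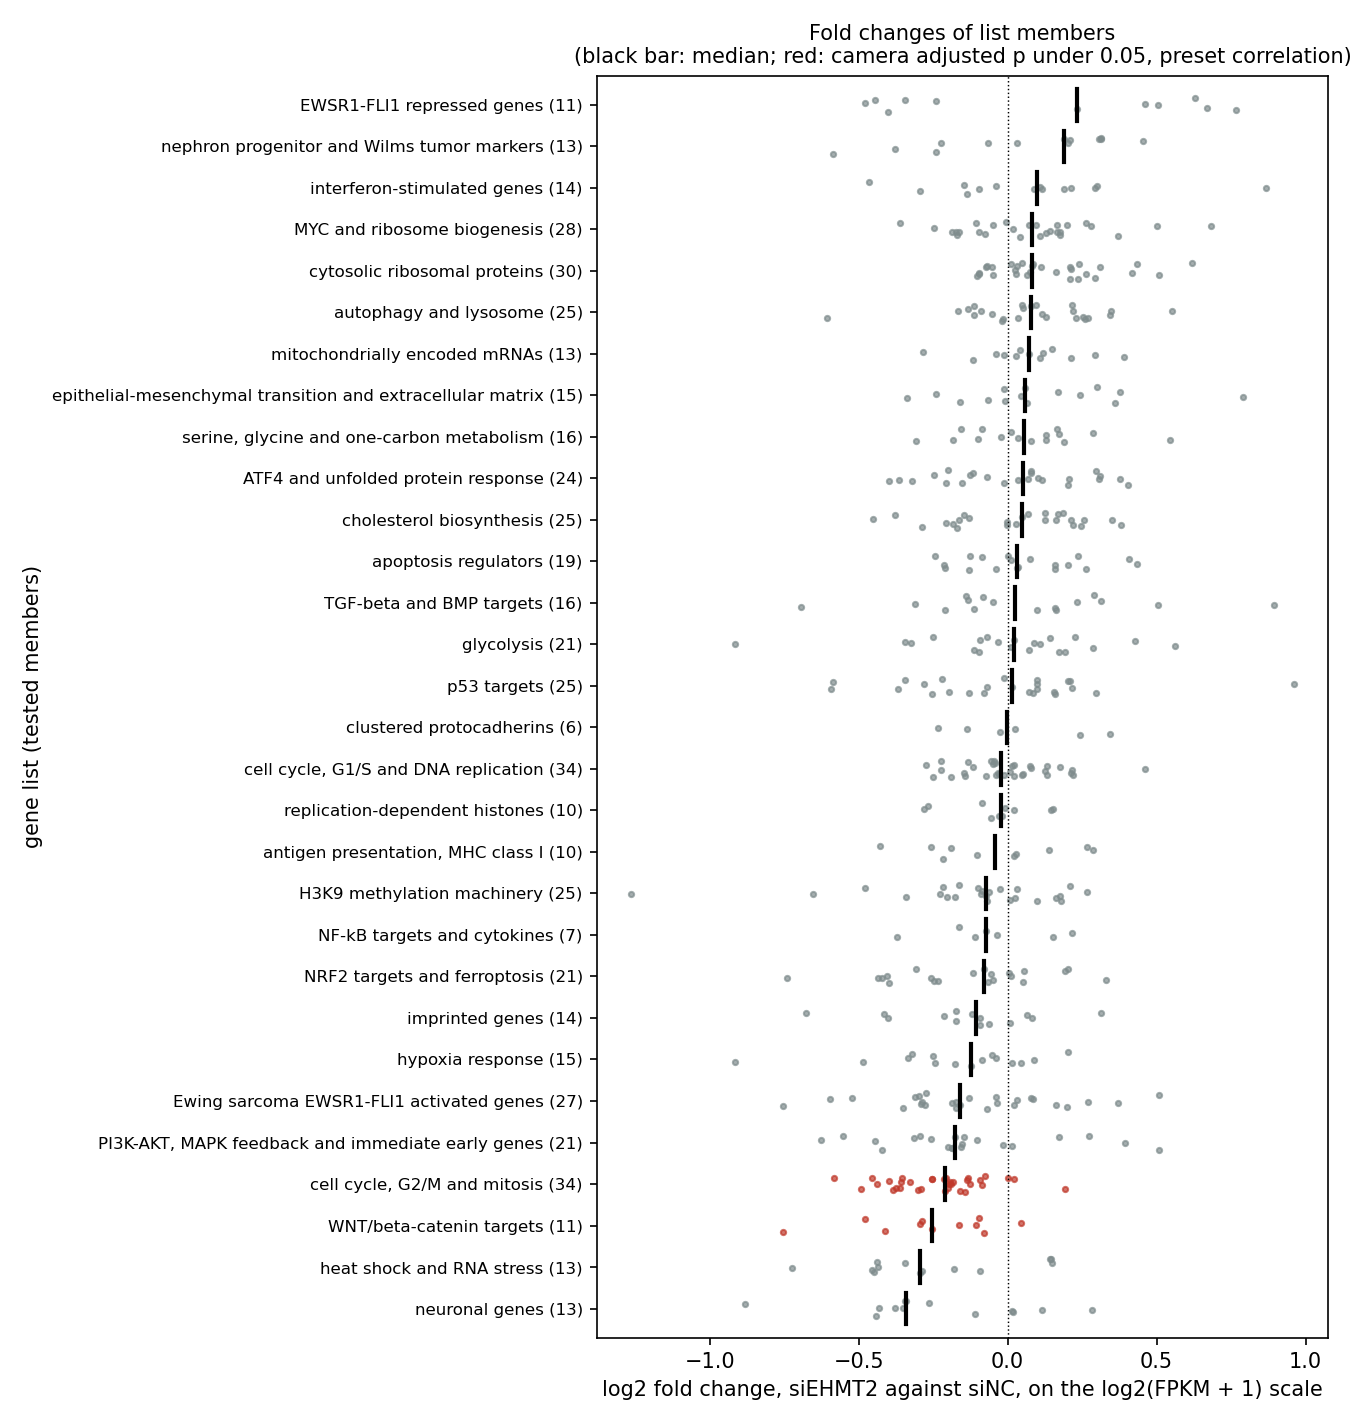
Log2 fold changes, siEHMT2 against siNC, of the tested members (points; number in brackets) of 30 gene lists on the log2(FPKM + 1) scale (x axis), with the median as a black bar; red lists have a camera adjusted p under 0.05 with the preset correlation. The G2/M and mitosis list has its median at −0.21 and the WNT/beta-catenin list at −0.25.

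Single members of other lists passed the test over all genes. The medians of the 28 lists that did not pass depended on single libraries. With 1 library left out, the median of 27 moved by over 1.5 times in at least 1 of 6 fits. The median of 11 took the other sign, and 7 lists passed with the preset correlation, in at least 1 fit. Without both libraries numbered 3, 14 lists passed, 10 lower and 4 higher. After GC correction 7 passed, all lower: the G2/M and WNT lists and those of NRF2 targets, PI3K-AKT and MAPK feedback, imprinted genes, neuronal genes and EWSR1-FLI1 activated genes. With an estimated correlation no list passed in any of these 8 fits, where 0 to 4 lists had an unadjusted p under 0.05. That test has few degrees of freedom with so few libraries, so its lack of calls is weak evidence against a list. The GC correction and the fit without both libraries numbered 3 were chosen after the data were seen. ACSL4, an enzyme that prepares polyunsaturated lipids in ferroptosis, fell from 10.1 ± 0.693 to 5.65 ± 0.326 FPKM (limma adjusted p = 0.0338). In the same list of NRF2 targets and ferroptosis genes, NFE2L2 also passed when adjusted over the list alone (9.85 against 13.5 FPKM), while the list as a whole (7 higher and 14 lower, median −0.08) had a camera adjusted p of 0.0835. That list passed without siNC replicate 2 (median −0.12, camera adjusted p = 0.0375; adjusted p = 0.790 with an estimated correlation). Its median was −0.011 without siEHMT2 replicate 3. NOLC1, a nucleolar protein gene in the MYC and ribosome biogenesis list, rose from 35.4 ± 0.168 to 57.5 ± 5.90 FPKM (limma adjusted p = 0.0422). NME1 of that list passed when adjusted over the list alone, and the list (17 higher and 11 lower, median 0.08) had a camera adjusted p of 0.519. Its median ran from 0.03 without siEHMT2 replicate 1 to 0.13 without siNC replicate 3. Without both libraries numbered 3 it passed (median 0.13, camera adjusted p = 0.00903; adjusted p = 0.613 with an estimated correlation). HOXC11, of the nephron progenitor list, fell from 21.2 ± 1.10 to 13.7 ± 0.268 FPKM (limma adjusted p = 0.0422), while 8 of 13 members of that list were higher (median 0.19, camera adjusted p = 0.980; median 0.10 without siEHMT2 replicate 3 or siNC replicate 2). ID3 passed in the TGF-beta and BMP target list, where ID2, at 69.7 against 114 FPKM, was lower when adjusted over the list alone, and the list had 8 members higher and 8 lower (median 0.02, camera adjusted p = 0.876; −0.06 without siEHMT2 replicate 2 and 0.11 without siEHMT2 replicate 3).

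Among the genes of histone H3 lysine 9 methylation, 9 of 25 were higher and 16 lower (median −0.07, camera adjusted p = 0.126; medians from −0.12 without siNC replicate 3 to −0.04 without siNC replicate 2). Without both libraries numbered 3 the list passed (median −0.09, camera adjusted p = 0.0358; adjusted p = 0.688 with an estimated correlation). None passed over all genes. Adjusted over the list alone, EHMT2, the demethylase gene JHDM1D (3.51 against 6.17 FPKM) and CBX5, which encodes the heterochromatin protein HP1 alpha (27.5 against 38.6 FPKM), were lower. Genes of PI3K-AKT and MAPK feedback had 5 members higher and 16 lower (median −0.18, camera adjusted p = 0.0678). They passed without siNC replicate 3 (median −0.19, camera adjusted p = 0.0116; adjusted p = 0.559 with an estimated correlation). In that list AKT1 (15.3 against 10.4 FPKM) was higher and DUSP6 (5.92 against 9.11), SPRED1 and SPRED2, which are feedback inhibitors of ERK signalling, were lower when adjusted over the list alone.

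In neuronal genes the median was −0.34 (4 higher and 9 lower, camera adjusted p = 0.0711), and VGF, at 0.739 against 2.27 FPKM, was lower when adjusted over the list alone. The neuronal median was −0.16 without siEHMT2 replicate 3 and −0.20 without siNC replicate 3. The list passed without siEHMT2 replicate 3 (camera adjusted p = 0.0313) and without siNC replicate 2 (median −0.28, camera adjusted p = 0.0375). Its adjusted p with an estimated correlation were 0.604 and 0.516. Imprinted genes had 4 members higher and 10 lower (median −0.11, camera adjusted p = 0.0939; median −0.06 without siNC replicate 1), with IGF2 (0.857 against 1.96 FPKM) lower when adjusted over the list alone. After GC correction the imprinted list passed (median −0.14, camera adjusted p = 0.0311; adjusted p = 0.313 with an estimated correlation). Of the p53 targets 13 were higher and 12 lower (camera adjusted p = 0.891), with a median of 0.02 and a mean of −0.02, so the signs of median and test differed. That median ran from −0.06 without siEHMT2 replicate 2 to 0.11 without siNC replicate 3. When adjusted over that list alone, TP53I3 (8.64 against 3.95 FPKM) was higher and TP53INP1 (1.85 against 3.29 FPKM) lower. Interferon-stimulated genes went both ways (8 higher and 6 lower, median 0.10, camera adjusted p = 0.876; median 0.02 without siNC replicate 1), with BST2 higher (5.51 against 2.67 FPKM) and OAS1 lower (2.37 against 3.65 FPKM) when adjusted over the list alone. In cholesterol biosynthesis (14 higher and 11 lower, median 0.05, camera adjusted p = 0.980; median −0.0010 without siNC replicate 3), IDI1 was lower when adjusted over the list alone (12.7 against 17.8 FPKM). Epithelial-mesenchymal transition and extracellular matrix genes had 9 members higher and 6 lower (median 0.06, camera adjusted p = 0.519). Medians ran from −0.02 without siEHMT2 replicate 2 to 0.17 without siEHMT2 replicate 3. In this list FN1 (20.5 against 11.1 FPKM) and MMP14 (19.2 against 14.6 FPKM) were higher when adjusted over the list alone. Over all genes the limma adjusted p was 0.110 for both.

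Besides the G1/S and hypoxia lists, 11 lists tested as a whole had no member past the threshold, over all genes or over the list alone. Cytosolic ribosomal protein genes had 23 members higher and 7 lower (median 0.08, camera adjusted p = 0.0728), with RPL11 at 305 against 198 FPKM. This list passed without siEHMT2 replicate 2 (median 0.18, camera adjusted p = 0.00176) and without siNC replicate 3 (median 0.18, camera adjusted p = 0.000457). With an estimated correlation these adjusted p were 0.914 and 0.780, and 0.985 over all libraries, where the correlation was 0.767. The ribosomal median was 0.0035 without siNC replicate 2 (camera adjusted p = 0.845). The other camera adjusted p-values were 0.375 for autophagy and lysosome genes (median 0.08), 0.637 for antigen presentation genes (median −0.04), 0.809 for replication-dependent histones (median −0.02) and 0.809 for NF-kB targets (median −0.07). For glycolysis genes (median 0.02), apoptosis regulators (median 0.03), serine, glycine and one-carbon metabolism genes (median 0.06) and mitochondrially encoded transcripts (median 0.07) it was 0.876. Clustered protocadherins (median −0.00075) and genes of ATF4 and the unfolded protein response stood at 0.980, and in the latter the median (0.05) and the direction of the test (lower) differed in sign. With 1 library left out, the medians of the ATF4, antigen presentation, histone, glycolysis, mitochondrially encoded and protocadherin lists took the other sign in at least 1 fit. The widest ranges were −0.15 to 0.06 for histones, −0.11 to 0.10 for glycolysis and −0.03 to 0.19 for mitochondrially encoded transcripts. None of these 6 lists passed with 1 library left out. Without both libraries numbered 3, glycolysis genes (median −0.08, camera adjusted p = 0.0179) and histones (median −0.28, camera adjusted p = 0.0227) passed as lower and autophagy genes (median 0.10, camera adjusted p = 0.0454) as higher. These adjusted p were 0.614, 0.613 and 0.613 with an estimated correlation.

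Heat shock genes differed within both groups. HSPA1A, a stress-induced chaperone gene whose reads can be shared with its near copy HSPA1B, was at 1.97, 2.04 and 9.80 FPKM in siEHMT2 replicates 1, 2 and 3 and at 8.66, 8.05 and 1.78 FPKM in siNC replicates 1, 2 and 3. Median deviations of the heat shock and hypoxia genes from their means over the libraries were −0.15, −0.22 and 0.12 in siEHMT2 and 0.25, 0.23 and −0.12 in siNC on the log2 scale. Between the groups, 10 of 13 heat shock genes were lower (median −0.29, camera adjusted p = 0.0728), with HSPA4 (27.0 against 36.9 FPKM) past the adjustment over the list alone. The heat shock list passed without siEHMT2 replicate 3 (median −0.38, camera adjusted p = 0.00293) and without siNC replicate 3 (median −0.45, camera adjusted p = 0.00485). With an estimated correlation these adjusted p were 0.786 and 0.780, and 0.985 over all libraries, where the correlation was 0.437. The heat shock median was −0.12 to −0.17 without any of the other 4 libraries. Of 15 hypoxia genes 11 were lower (median −0.12, camera adjusted p = 0.0678), among them SLC2A1, at 5.13 against 10.1 FPKM, with a limma adjusted p of 0.1004. The hypoxia list too passed without siEHMT2 replicate 3 (median −0.26, camera adjusted p = 0.0010) and without siNC replicate 3 (median −0.32, camera adjusted p = 0.00236). Their adjusted p with an estimated correlation were 0.786 and 0.780, and 0.985 over all libraries, where the correlation was 0.479. The hypoxia median was −0.07 without siEHMT2 replicate 2.

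**Figure D3:**
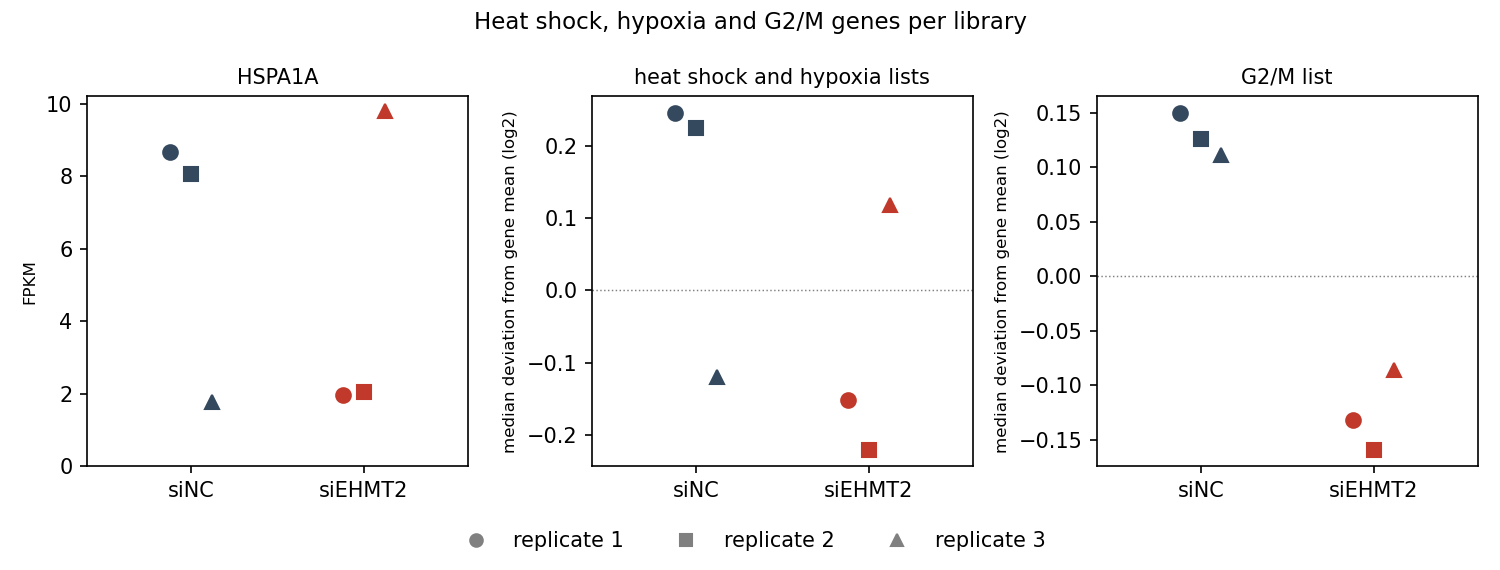
HSPA1A (left, FPKM from 0) and the median deviation of list members from their mean over 6 libraries (middle and right, log2) in each library; colours and x axis give the group, symbols the replicate. HSPA1A is near 2 FPKM in siEHMT2 replicates 1 and 2 and siNC replicate 3, while the G2/M list is below 0 in all 3 siEHMT2 libraries and above 0 in all 3 siNC libraries.

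Levels of lineage markers were described over the 6 libraries without a comparison of the groups. Of 32 genes known to be activated by EWSR1-FLI1, 27 had a mean of at least 1 FPKM (median of the list 17.9 FPKM), among them NKX2-2 at 123.01 ± 11.01 FPKM (SD, n = 6), STEAP1 at 26.4 ± 3.58, PRKCB at 22.9 ± 2.78 and NR0B1 at 9.63 ± 1.70. Several other members, such as CCND1 and EZH2, are expressed in many cell types. Of 29 nephron progenitor and Wilms tumor markers, 13 had a mean of at least 1 FPKM (median 0.703 FPKM). SIX2 was at 0.164 ± 0.054 FPKM, PAX2 at 0.079 ± 0.032 and WT1 at 1.19 ± 0.267, whereas IGF2BP1 was at 38.7 ± 4.47, HOXD11 at 30.0 ± 9.14 and LIN28B at 13.6 ± 2.19. Too few members of 5 lists were tested for a list test. Of the fibroblast and pericyte markers 4 of 15 reached 1 FPKM, with THY1 the highest at 24.9 FPKM, of the endothelial markers 1 of 13 (EGFL7, 24.1), of the leukocyte and erythroid markers 0 of 19 and of the kidney epithelium markers 2 of 18 (PODXL, 19.3, and KRT18, 5.20). None of these 7 genes passed the test between the groups. Of 32 germline and cancer-testis genes 3 were tested, all higher without passing over all genes: XAGE1A (16.4 against 10.2 FPKM), PRAME (74.1 against 67.5 FPKM) and STAG3. XAGE1A, which has near copies, passed when adjusted over the 3 tested list members alone (limma adjusted p over all genes 0.109).

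**Figure D4:**
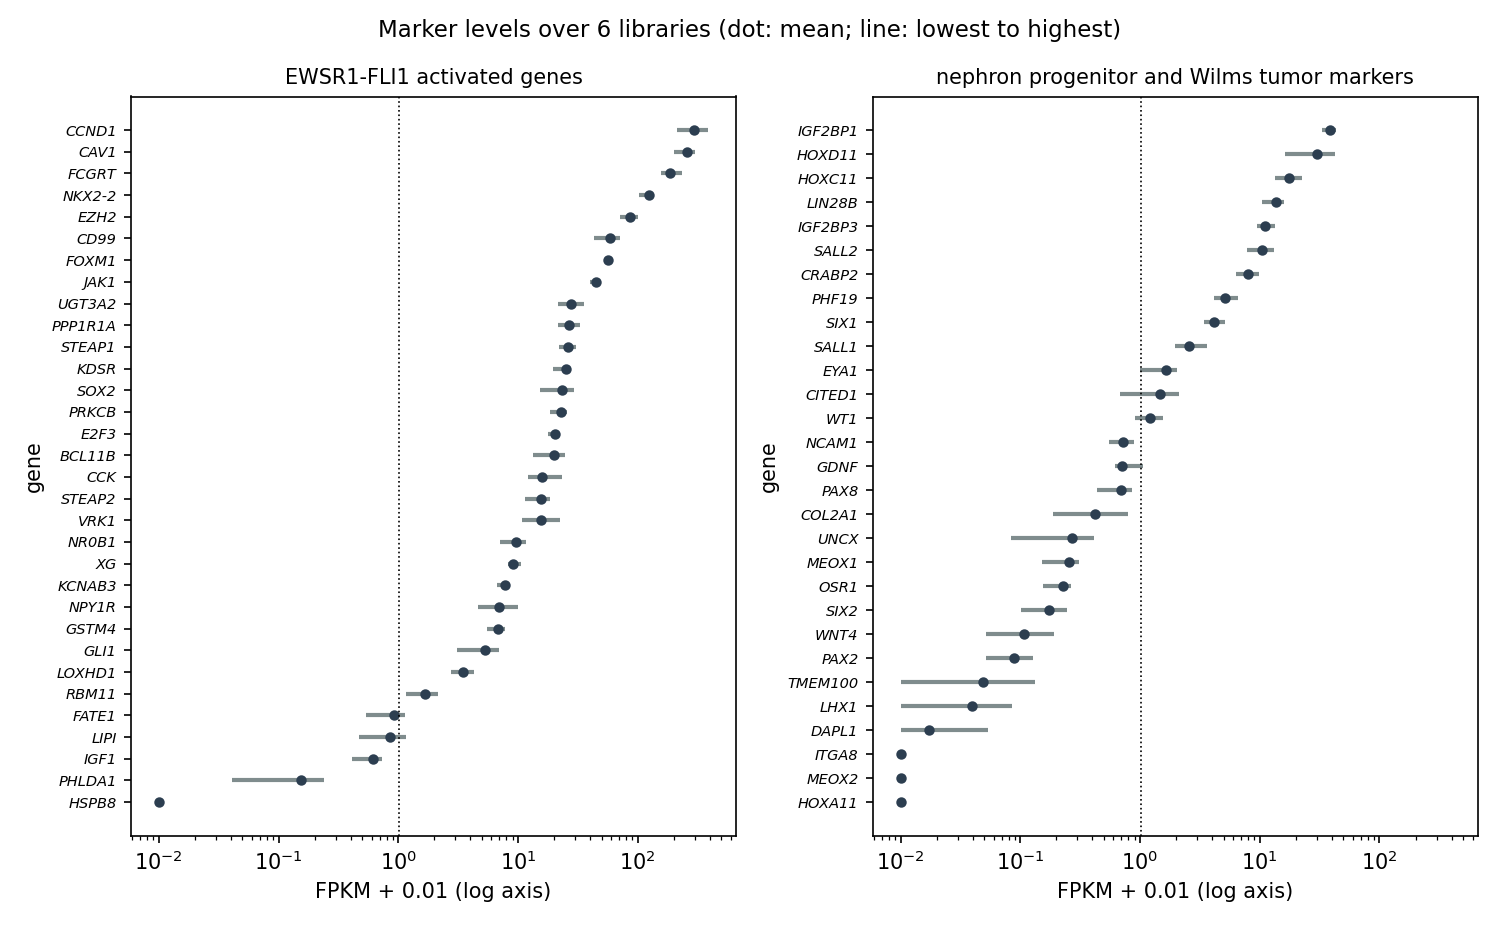
Mean FPKM + 0.01 over 6 libraries (x axis, log scale; dots) and the range from the lowest to the highest library (lines) of EWSR1-FLI1 activated genes (left) and nephron progenitor and Wilms tumor markers (right); the dotted line is at 1 FPKM. The left list has 27 of 32 genes at or above 1 FPKM, the right list 13 of 29.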

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

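The GC correction, the genes with a GC value, gene-by-gene array weights, protein-coding genes alone, both number-3 libraries left out and alternatives with an estimated correlation were chosen after seeing the data. The 25 named genes past the threshold had the same direction in each of the 23 alternative fits that tested them, though not the call: 0 kept it with no filter, with the replicate block (with or without GC correction) and without siEHMT2 replicate 2, siNC replicate 1 or siNC replicate 2. Their groups do not overlap, so leaving out libraries could not turn their direction, and the kept direction is no independent support. Against 71 genes in the reported fit, 69 and 68 were called with pseudocounts of 0.1 and 0.5, 134 with a mean of at least 5 FPKM (fewer genes tested), 30 without the trend, 113 after GC correction (55 higher and 58 lower; 52 shared), 112 over the genes with a GC value (71 higher, 41 lower), 218 over protein-coding genes, and 0 with limma and no filter, where 3641 genes had an unadjusted p under 0.05. Rescaling each library to the same sum, as in TPM, gave 28 genes, 8 higher and 20 lower against 44 and 27. Its pseudocount of 1 is then smaller relative to the values. Pseudocounts of 0.1 and 0.5 without rescaling kept 43 higher genes each, so this does not account for the fewer rises. Rescaling moved the median log2 fold change of all genes from 0.0145 to −0.0287. The excess of rises thus depended on the scale of the libraries. Median-of-ratios scaling gave 56 (31 and 25) and quantile normalization 83 (46 and 37), and no scaling moved the median of all genes by over 0.1. Array weights gave 3797 genes and gene-by-gene weights 2936; the default weights stopped before converging, and both give siEHMT2 replicate 3 and siNC replicate 3 the lowest weights. Leaving out both of these libraries gave 1890 genes, 71 of them shared. Where fewer genes or samples do not account for a moved count, the cause was not tested. Genes changed at least 2-fold were 14 in the reported fit, 0 without a filter, 9 without the trend, 85 and 66 with the 2 kinds of array weights and 81 without both number-3 libraries. Called lists were 2 in the reported fit, 5 without a filter (with hypoxia, PI3K-AKT and EWSR1-FLI1 activated genes), 4 at 5 FPKM (with hypoxia and EWSR1-FLI1 activated genes), 4 and 5 with array weights (with hypoxia and heat shock, and PI3K-AKT with gene-by-gene weights), 7 after GC correction, 14 without both number-3 libraries and 0 with an estimated correlation, where the G2/M list (median −0.21) and the WNT list (−0.25) lost their call; with that correlation 0 lists were called under each of the 23 other alternatives too. The WNT median there was −0.30 and −0.28 with pseudocounts of 0.1 and 0.5, −0.29 at 5 FPKM, −0.34 rescaled, −0.27 with median-of-ratios scaling, −0.25 with quantile normalization and after GC correction, and the G2/M median −0.26 rescaled, −0.23 and −0.24 with the other scalings, −0.28 with both kinds of array weights and −0.15 after GC correction. With that correlation and siEHMT2 replicate 1, 2 or 3, siNC replicate 1, 2 or 3 or both number-3 libraries left out, G2/M medians were −0.23, −0.20, −0.25, −0.21, −0.21, −0.24 and −0.31 and WNT medians −0.24, −0.26, −0.20, −0.27, −0.27, −0.19 and −0.17. Over all libraries the estimated correlation was 0.0532 for the G2/M list and 0.0054 for the WNT list, the latter below the preset 0.01. A higher correlation thus does not account for the lost call of the WNT list. With an estimated correlation, camera has the degrees of freedom of the few libraries and so little power. Both lists kept their call under each alternative with the preset correlation, the WNT median moving to −0.15 and −0.17 with array weights, −0.17 without both number-3 libraries and −0.14 without a filter (21 members). With single libraries left out, 0 to 172 genes, 0 to 36 genes changed at least 2-fold and 2 to 6 lists were called, and EHMT2 ranged from −1.58 to −1.08. EHMT2 passed the threshold at 5 FPKM (−1.27), over the genes with a GC value (−1.27) and over protein-coding genes (−1.27), where fewer genes are tested, and with array weights (−1.56 and −1.55), GC correction (−1.37) and without both number-3 libraries (−1.67); its adjusted p ranged from 0.000364 to 0.259. PRAME, not past the threshold, reversed to −0.0015 with array weights. Named genes other than EHMT2 gave 136 values that newly passed, 224 that no longer passed and 1383 on their own side. Summing rows of 1 symbol changed nothing, since no symbol repeats. Marker counts at 5 FPKM were 25 and 8. The depth of the libraries is unknown beyond its relative size, so no limit of detection is given.

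The labels do not say whether the replicate numbers mark a pairing. Correlations of the same-numbered libraries' deviations were −0.35, 0.087 and −0.39, and siEHMT2 replicate 1 correlated best with siNC replicate 3 (0.48). These values show no pairing by number but cannot exclude one. With the replicate block, limma called 0 genes and 0 changed at least 2-fold (1845 with an unadjusted p under 0.05) and 6 lists, the G2/M and WNT lists and those of ribosomal proteins (adjusted p 0.0246), hypoxia (0.0482), PI3K-AKT and MAPK feedback and EWSR1-FLI1 activated genes (0.0449 for both); with an estimated correlation the block gave 0 lists, and these adjusted p were 0.959, 0.959, 0.805 and 0.805. With the block and the GC correction together it was 0, 0 and 8, and 0 lists with an estimated correlation.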

Other observations

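Other called genes, chosen after their values were seen, included both subunits of glucosidase II, an enzyme of protein folding in the endoplasmic reticulum: GANAB rose from 60.8 ± 7.56 to 103 ± 10.2 FPKM (SD, n = 3) and PRKCSH from 31.2 ± 0.708 to 45.4 ± 0.782. A second tropomyosin gene, TPM2, rose from 8.53 ± 0.742 to 16.1 ± 0.803 FPKM. The sulfotransferase gene CHST14 rose from 8.95 ± 0.875 to 16.6 ± 1.04 FPKM and the chondroitin synthesis gene CHPF2 from 6.42 ± 0.497 to 11.1 ± 1.02. PRMT6, an arginine methyltransferase of histones, rose from 14.2 ± 1.54 to 26.8 ± 3.79 FPKM. The sorting nexin genes SNX3 and SNX6 fell from 47.8 ± 1.21 to 28.2 ± 4.73 and from 17.8 ± 0.304 to 10.2 ± 1.14 FPKM, and ZMYND11, a reader of methylated histone H3, fell from 17.5 ± 0.917 to 10.1 ± 0.385. All 9 had a limma adjusted p under 0.05, from 0.0285 to 0.0475. None of them passed without siEHMT2 replicate 2 or without siNC replicate 1, where limma called 0 genes and 1658 and 1526 had an unadjusted p under 0.05.

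Tests of the lower G1/S level, of the GC trend as a whole cause, of the level of EHMT2 (both) and of a swap were chosen only after the result was seen, and the other tests of a GC trend rest on a GC correction chosen after the data were seen.

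The G2/M list was lower in siEHMT2 (median −0.21), and a GC trend between the libraries may carry part of this. After GC correction the median was −0.146, with a 95% interval of −0.232 to −0.0781 (10000 resamples of the members). Its upper bound of −0.0781 argues against the trend as the whole cause among these libraries. The interval covers members and no spread between libraries. It spans the −0.104 that would mark the larger part, which cannot be told apart. Without siEHMT2 replicate 3 the median was −0.252, which argues against that library alone. In the G1/S list 16 members were higher and 18 lower, with a median of −0.0219. Its 95% interval was −0.0496 to 0.0482 (10000 resamples of the members). The whole interval lay above −0.104, the mark set for lower proliferation at large. However, the members vary together (estimated correlation 0.485). Medians with 1 library left out ran from −0.0741 to 0.0792, beyond the interval, so the test cannot tell. The median lay above −0.104 by less than the SD of single members, 0.157, and the interval covers no spread between libraries. Lower proliferation thus stays open, as do the knockdown and any unrecorded difference between the groups.

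Fold changes rose with GC content (rho 0.387), and siEHMT2 replicate 3 differed from replicates 1 and 2 along GC (rho 0.474). Without this library rho was 0.178 (95% interval 0.160 to 0.195, 500 resamples of genes), which argues against it as the whole cause among these libraries. The interval covers genes, which are not independent replicates, and no spread between libraries. Deviations of the other single libraries had a rho of −0.339 to 0.110, so whether the remaining trend goes with the groups cannot be told. Other library preparation differences could add to the trend and were not tested. No biological explanation was tested.

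Heat shock and hypoxia genes were low in siEHMT2 replicates 1 and 2 and siNC replicate 3, and high in the other 3 libraries. A GC trend is argued against for these libraries: after correction, siEHMT2 replicate 3 lay 0.372 above replicates 1 and 2. The 95% interval over resampled members lay above the 0.154 that would be needed. The level of EHMT2 as the whole cause is argued against: siEHMT2 replicate 3, with 16.2 FPKM of EHMT2, lay at 0.118 and siNC replicate 3, with 22.7 FPKM, at −0.120, higher by 0.238 where lower was needed, while libraries of near-equal EHMT2 differed by at most 0.0689; a part in the pattern stays open. A swap of these libraries is argued against by EHMT2 in siNC replicate 3, 1.41 above siEHMT2 replicates 1 and 2 on the log2 scale and 0.256 from siNC replicates 1 and 2. Handling or density of the cultures may differ between the libraries and stays open, since the labels give no batch.

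With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. As many genes as the 71 of the real grouping came from 1 of 10 splits, the real one, and the highest other gave 35; for genes changed at least 2-fold it was 2 of 10 (real 14, highest other 21). As many lists as the real 2 came from 10 of 10 splits, and the highest other gave 8. The number of list calls with the preset correlation, those of the G2/M and WNT lists, thus does not set the real grouping apart. The split with 35 genes and 21 changed at least 2-fold parts siEHMT2 replicates 1 and 2 and siNC replicate 3 from the rest, as the heat shock genes do.

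FLI1 was at 5.46 ± 0.866 FPKM (SD, n = 6) and EWSR1 at 25.4 ± 1.17, both chosen after their values were seen. SK-NEP-1 is known from outside these data to have been reported with an Ewing sarcoma fusion, which gene-level values do not show, and whether an Ewing sarcoma programme is active in these cells was not tested.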
